A study of Mus musculus with 12 samples.

How the data were processed

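RNA was measured by sequencing in 12 libraries of mouse tibialis anterior, a fast-twitch muscle of the lower leg. Per the labels, 4 libraries came from muscle given a matrix gel, 4 from muscle given phosphate-buffered saline (PBS), the vehicle, and 4 from uninjured muscle. The labels' protocol gives an injected volume of 50 µl, a gel concentration of 6 mg per ml, the left leg for the gel and the right leg for PBS, and extraction and library construction by BGI. The side of the body therefore goes with the treatment in every gel and PBS library. The kind of injury and the time between injection and collection are not given in the sources used here.

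The deposited values are counts of reads per gene symbol, 1 column for each library, and the authors had not normalised them. Alignment used STAR against the mouse genome build mm39, per the submitters' processing notes, which also name edgeR, without versions. The counting program, its strand setting, its treatment of reads with several matches and the gene annotation are not given in the sources used here. Reads from overlapping or antisense genes, from pseudogenes and from near-identical copies therefore cannot be assigned with certainty, which concerns Hmga2-ps1, Rn45s, the metallothioneins, the ribosomal proteins and the major histocompatibility genes among those named. The reference available was of another build, so no coordinates are given.

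Each library held values for 26264 genes. Library totals ran from 15626086 to 22182483 counts, and every column was matched to a library, with 0 columns left over. No 2 libraries of a group agreed within sampling noise: the chi-square statistic per gene between replicates, over genes with at least 20 reads in the pair, was 6.51 or higher. Intervals computed from counts alone cover counting error only.

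Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 13499, and libraries were scaled by the trimmed mean of M values. A quasi-likelihood model with robust estimation was fitted to all 12 libraries with 1 coefficient for each group, leaving 9 residual degrees of freedom. PBS was compared with uninjured, gel with PBS and gel with uninjured by quasi-likelihood F tests. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and "rose" and "fell" are used for genes or lists past that threshold. Log2 fold changes are given with a standard error (SE), which is the fold change divided by the square root of its F statistic. Levels are in CPM, the unit of edgeR in which counts are scaled to a common library total, with the standard deviation (SD) over 4 libraries, and log2 CPM used a prior count of 2. The p-values treat the 4 libraries of a group as replicates, and the deposited names give these 4 different numbers, read here as animal numbers.

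The design, the alternatives, the rule for naming genes and 44 gene lists were fixed before the data were examined. The lists covered fast-fibre and slow-fibre contractile genes, developmental fibre genes, satellite cells, atrophy, denervation, the neuromuscular junction, proteasome and autophagy, the nuclear and mitochondrial respiratory chain subunits, citrate cycle, fatty acid oxidation, glycolysis, lipid synthesis, interstitial matrix, basement membrane, matrix remodelling, transforming growth factor signalling, markers of 13 other cell types, cytokines, interferon response, antigen presentation, proliferation, heat shock, protein and amino-acid stress, antioxidants, immediate-early genes, the circadian clock, growth factors, calcium handling and ribosomal proteins. Lists with at least 4 tested members, 40 in all, were tested with camera from limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and adjustment over the lists. The other 4 had too few tested members: 0 for the mitochondrial genome subunits and 2 each for T and NK cells, erythroid genes and keratinocytes. Every list call was lost when camera estimated the correlation for each list, and that adjusted p is given beside each call. The members of a list that passed edgeR are counted over all genes tested and also adjusted over the list alone. A list's level in a library is the mean log2 CPM of its members minus the mean of the uninjured libraries.

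For each comparison the rule for naming genes took the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, up to 4 members with the smallest p from each list past camera, and 13 genes fixed by name. It also took the 10 genes with the strongest calls in opposite directions. Some of these are given in the text. Genes named outside this rule in the closing section were chosen after their values were seen. Where a gene had 1 to 3 counts in a group, the ratio of counts is given with a 95% exact interval.

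Gel and PBS libraries with the same number are treated as legs of the same animal, because the labels place gel on the left and PBS on the right leg and the deposited names give both libraries of a number the same animal number. Their deviations from the group means correlated across genes at 0.143, -0.0559, 0.311 and 0.0797 for numbers 1 to 4. A library of another number correlated more highly for numbers 1, 2 and 4, at up to 0.178, 0.113 and 0.196, so these values alone do not show the pairing. A fit with this number as a block, on the 8 libraries of gel and PBS, is an alternative. Its value stands beside a result where it changed the call. A call that changed there may have changed through the block or through leaving out the uninjured libraries. The uninjured libraries carry other animal numbers.

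The alternatives were the size factors of DESeq2 1.42.0, no filter or at least 1 CPM in 4 libraries, the DESeq2 Wald test, limma voom, a fit on the 2 groups compared alone, the block, a minimum of 2-fold, an adjusted p under 0.01, and leaving out each library in turn. For lists they were an estimated correlation, fry and camera on ranks. An alternative without the gel and PBS libraries numbered 3 was chosen after seeing the data.

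The steps were tested on simulated counts for 13499 genes, with known fold changes in a subset. For PBS against uninjured, edgeR recovered 7.58% of genes changed 1.5-fold, 53.1% of those changed 2-fold and 82.9% of those changed 4-fold, and 6 of 117 calls were false. For gel against PBS the shares were 17.2%, 41.8% and 89.9%, with 27 of 137 calls false, and for gel against uninjured 14.9%, 50.8% and 92.4%, with 13 of 133 false. A list shifted 2-fold was found in each comparison and 0 of 39 unchanged lists were called. The simulated genes were drawn independently of each other. These lists therefore do not show how often camera calls an unchanged list whose genes are correlated. Comparisons that share a group were set beside 20 simulations of unchanged groups, the overlap of independent lists, and splits of the shared libraries into pairs.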

Results

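Gene expression was measured in 12 libraries of mouse tibialis anterior muscle, 4 from uninjured muscle, 4 from muscle injected with PBS and 4 from muscle injected with a matrix gel, which is a hydrogel made from the extracellular matrix of a tissue. The series title names recovery from acute and disuse muscle injury as the setting. Library totals were 15970781 to 18787964 counts in the uninjured group, 16714543 to 20488409 in the PBS group and 15626086 to 22182483 in the gel group. Between 15040 and 17660 genes had a count in each library, and the 10 most abundant genes took 26.0% to 34.2% of the counts.

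Gel library 3 stood apart from the other gel libraries. On the first principal component, which held 50.7% of the variance, gel libraries 1, 2 and 4 lay at -67.4, -84.1 and -91.4, and gel library 3 lay at 5.39. The PBS libraries lay between 17.2 and 46.5 and the uninjured libraries between 21.5 and 37.2. The second component, with 13.4%, placed the uninjured libraries between 26.8 and 32.8 and the PBS libraries between -32.3 and -18.8, with gel library 3 at -29.2.

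**Figure D1:**
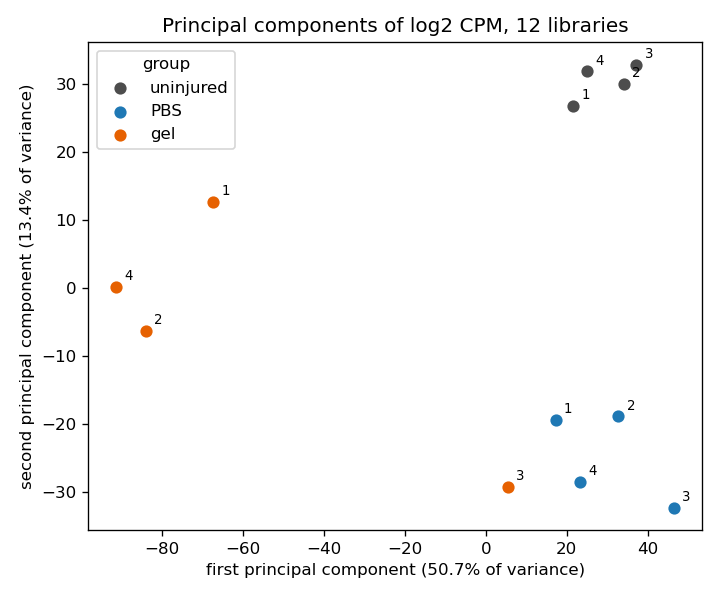
Principal components of log2 CPM in the 12 libraries, with the first component (50.7% of the variance) on the x axis and the second (13.4%) on the y axis, each point a library with its number and colours giving the group. Gel libraries 1, 2 and 4 lie at -67.4 or lower on the first component and gel library 3 lies at 5.39.

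PBS-injected muscle was compared with uninjured muscle. The PBS leg is taken here as the other leg of an animal given the gel, and uninjured muscle came from other animals. The comparison therefore cannot part injury and injection from the gel in the other leg or from the set of animals. Genes for the metal-binding metallothioneins were among the largest falls: Mt1 went from 504 ± 166 CPM (SD, n = 4) in uninjured muscle to 44.9 ± 11.6 CPM in PBS muscle, and Mt2 from 282 ± 105 to 11.0 ± 7.58 CPM. The transcription factor genes Cebpd and Nr4a3, the kinase gene Map3k6 and Ddit4, an inhibitor of mTOR signalling, fell as well. The largest rises included Frzb, which encodes a secreted Wnt antagonist, and Tnfaip3, which encodes an inhibitor of NF-kappaB signalling. In edgeR the log2 fold change was -3.49 ± 0.29 (SE) for Mt1 (adjusted p = 3.99e-05) and 2.02 ± 0.25 for Frzb (adjusted p = 0.000276). The pseudogene Hmga2-ps1 fell by 4.26 on the log2 scale and Odf3l2 by 5.20, although reads at either may belong to other transcripts. The remaining large falls were in Doc2b and Zfand4, at -3.40 and -3.10, and the call of Zfand4 was lost without uninjured library 4 (adjusted p = 0.0537).

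The other large rises in PBS muscle were in genes of low abundance. Akap5, which encodes an anchoring protein for protein kinase A, rose by 3.68 ± 0.80 on the log2 scale. Sox11, a transcription factor gene, had 46 counts in PBS muscle and 2 in uninjured muscle, a ratio of 20.5 with a 95% exact interval of 5.36 to 174. Its edgeR call was lost without uninjured library 2 (adjusted p = 0.0541) or 3 (adjusted p = 0.0539). Zfp750, Ak4, Dach2 and Arhgap28 rose between 2.01 and 3.12. Their calls were lost without uninjured library 3 for Zfp750 (adjusted p = 0.0627) and Arhgap28 (0.0521), without uninjured library 2 for Zfp750 (0.0613) and Ak4 (0.0600), and without uninjured library 1 for Ak4 (0.0538) and Dach2 (0.0716). The Dach2 call was also lost without uninjured library 4 (0.0821), PBS library 1 (0.0665), PBS library 2 (0.0667) or PBS library 3 (0.0618), that of Ak4 without PBS library 2 (0.0571) or PBS library 3 (0.0587), and that of Zfp750 without PBS library 2 (0.0571). With limma voom the adjusted p of Sox11, Zfp750, Ak4, Dach2 and Arhgap28 rose to between 0.0508 and 0.0882.

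Of 18 atrophy genes, 8 fell and 0 rose in PBS muscle, also when adjusted over the list alone (camera adjusted p = 4.23e-07; adjusted p = 0.343 with an estimated correlation). The members with the smallest p were Cebpd, Mt1, Ddit4 and Mt2, and none of these encodes an enzyme of protein breakdown. Cebpd fell by 2.90 ± 0.23 on the log2 scale, Ddit4 by 2.94 ± 0.35 and Trim63, a muscle ubiquitin ligase, by 1.05 ± 0.18 (edgeR adjusted p = 0.00348). Fbxo32, the other classical atrophy ligase, was at -0.35 ± 0.22 (adjusted p = 0.383) and the growth inhibitor Mstn at -0.33 ± 0.23 (adjusted p = 0.438). Of 9 tendon cell markers, 4 fell and 0 rose, or 6 adjusted over the list alone (camera adjusted p = 3.09e-06; adjusted p = 0.343 with an estimated correlation). Thbs4, a matrix protein gene of tendon, went from 151 ± 13.6 to 77.6 ± 13.8 CPM and fell by 0.96 ± 0.15. Fmod, which encodes the collagen-binding fibromodulin, fell by 1.97 ± 0.36.

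Ribosomal protein genes were lower in PBS muscle, with 6 of 30 lower and 0 higher over all genes and 18 lower adjusted over the list alone (camera adjusted p = 6.56e-09; adjusted p = 0.584 with an estimated correlation). The median log2 fold change of this list was -0.33. Rps14 and Rpl14 fell by 0.52 ± 0.13 and 0.49 ± 0.13, calls that were both lost without PBS library 1 (edgeR adjusted p = 0.105 and 0.107), PBS library 2 (0.112 for both), or uninjured library 1 (0.0582 and 0.0810), 2 (0.106 and 0.0777), 3 (0.0821 and 0.111) or 4 (0.0845 and 0.0757), and for Rpl14 also without PBS library 4 (0.0760). Rn45s, a ribosomal RNA precursor, was at 92.8 ± 16.4 CPM in uninjured and 26.4 ± 7.69 CPM in PBS libraries. Whether the Rn45s level follows the muscle or the preparation of the libraries was not tested, here or in the comparisons below.

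The fatty acid oxidation and citrate cycle lists were higher in PBS muscle. Of 22 fatty acid oxidation genes, 4 rose and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00140; adjusted p = 0.655 with an estimated correlation). Acsl1, which activates long-chain fatty acids, rose by 0.85 ± 0.18 on the log2 scale. The member that fell was Ucp3, a mitochondrial uncoupling protein gene, from 486 ± 125 to 157 ± 24.4 CPM. Of 17 citrate cycle enzymes, 1 rose, or 4 adjusted over the list alone (camera adjusted p = 0.00816; adjusted p = 0.521 with an estimated correlation), with a median of 0.21. The nuclear respiratory chain list was not called, with a median of -0.08 and 2 of 42 members lower (camera adjusted p = 0.134), and passed as lower without PBS library 3 (0.00607). The citrate cycle member that rose, Dlst, at 0.55 ± 0.14, lost its call without PBS library 1 (edgeR adjusted p = 0.0764), 2 (0.109) or 3 (0.0610), or uninjured library 1 (0.0771), 2 (0.0921), 3 (0.0914) or 4 (0.0968). Of 14 calcium handling and excitation genes, 1 rose, or 2 adjusted over the list alone (camera adjusted p = 0.0161; adjusted p = 0.584 with an estimated correlation). It was Atp1b1, a sodium pump subunit gene, at 1.16 ± 0.25, whose call was lost without PBS library 2 (adjusted p = 0.0505), uninjured library 2 (0.0504) or uninjured library 3 (0.0535).

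Macrophage markers as a list were not called between PBS and uninjured muscle (camera adjusted p = 0.749, median log2 fold change -0.15). Adgre1, a macrophage surface marker, was at 0.536 ± 0.447 CPM in PBS muscle and 0.520 ± 0.435 CPM in uninjured muscle, and Col1a1, a fibrillar collagen gene, at 262 ± 126 and 243 ± 66.5 CPM. The log2 fold changes of Adgre1, Mki67, Col1a1, Col3a1 and Postn were 0.06 ± 1.13, 0.27 ± 0.82, 0.11 ± 0.54, 0.08 ± 0.57 and -0.33 ± 0.76. Those of the fibre genes Myh3, Myog, Myh7 and Myh4 were 0.58 ± 0.47, 1.37 ± 0.46, -1.21 ± 1.28 and -0.18 ± 0.18, and that of the satellite cell gene Pax7 was 0.91 ± 0.37. In edgeR the smallest adjusted p of these 10 genes was 0.103, for Myog, which passed in DESeq2 (adjusted p = 0.00862). The sign turned without PBS library 1 for Adgre1, Col1a1 and Col3a1 (-0.58, -0.28 and -0.40), without PBS library 4 for Mki67 (-0.06) and without uninjured library 4 for Adgre1 and Myh7 (-0.06 and 1.54). It also turned without uninjured library 2 for Adgre1 and Col3a1 (-0.36 and -0.04), and without uninjured library 3 for Col1a1 and Col3a1 (-0.03 for both). With limma voom Col3a1 was at -0.04. The developmental fibre list was not called, with 2 of 16 members higher (camera adjusted p = 0.0706). It passed without gel library 4 (0.0437), PBS library 2 (0.0047) or 3 (0.0199), or uninjured library 4 (0.0478). The fast-fibre and proteasome lists were not called either, with 3 of 14 and 2 of 32 members lower (0.0595 for both). They passed with some libraries left out, at 0.0191 and 0.00352 at the lowest.

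In total 833 of 13499 genes differed between PBS and uninjured muscle, 376 higher and 457 lower, and 104 and 180 of these changed at least 2-fold. The groups did not overlap for 804 of the 833 genes, and for 20.6% of all genes tested, where chance gives 2.86%. The count was 1345 with the DESeq2 Wald test, 2339 with the 2 groups alone, where 1192 were higher and 1147 lower, and 1693 without gel library 3, which adds to the shared estimate of spread. It was 443, 410 and 543 without PBS library 1, 2 or 3, and 438, 393 and 378 without uninjured library 2, 3 or 4.

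**Figure D2:**
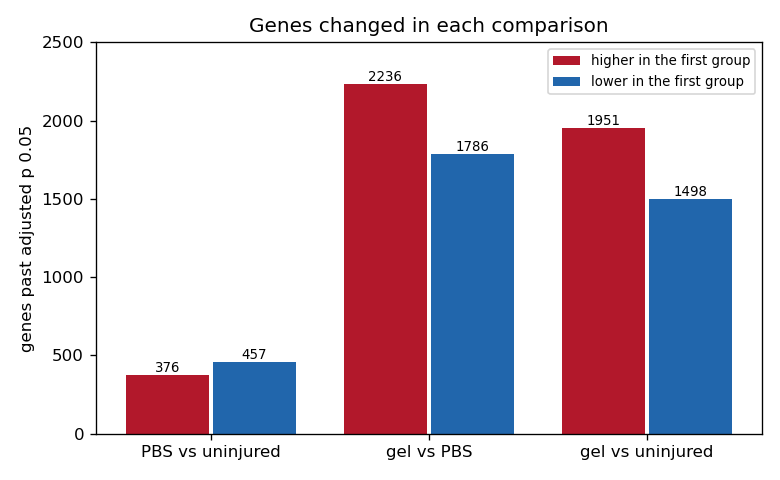
Number of genes past an edgeR adjusted p of 0.05 in each comparison (y axis), with red bars for genes higher and blue bars for genes lower in the group named first. PBS against uninjured muscle has 376 and 457 genes, gel against PBS 2236 and 1786, and gel against uninjured 1951 and 1498.

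Gel-treated muscle was compared with PBS-treated muscle, which gives the difference between the gel and its vehicle. Macrophage genes rose most. Of 23 macrophage and monocyte markers, 20 rose and 0 fell, or 21 adjusted over the list alone (camera adjusted p = 1.34e-06; adjusted p = 0.702 with an estimated correlation). Trem2, a lipid-sensing receptor gene of macrophages, went from 0.383 ± 0.252 CPM (SD, n = 4) in PBS muscle to 60.8 ± 44.5 CPM in gel muscle, and the complement gene C1qa from 4.07 ± 1.43 to 77.9 ± 45.0 CPM. Log2 fold changes were 4.26 ± 0.64 (SE) for C1qa (edgeR adjusted p = 0.00236), 4.55 ± 0.71 for C1qc and 2.41 ± 0.44 for Folr2, a marker of resident macrophages. The level of the list above uninjured muscle was 3.81 to 4.63 in gel libraries 1, 2 and 4 and 0.87 in gel library 3, with PBS libraries at 0.38 or lower.

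Trem2 was among the 8 genes named for the largest rises over PBS. Msr1, a scavenger receptor gene, had 694 counts in gel muscle and 2 in PBS muscle, a ratio of 306 with a 95% exact interval of 84.4 to 2531. The others, with Trem2, were Cd300c2, Cd180, Atp6v0d2, Ly9, Gpnmb and Ms4a7, with log2 fold changes between 6.77 ± 1.20 and 7.61 ± 1.14. In limma voom 7 of the 8 calls were lost, with adjusted p between 0.0582 for Msr1 and 0.266 for Cd180. Gpnmb kept its call there but lost it with the animal as a block (adjusted p = 0.0630). With voom the calls of Adgre1 (adjusted p = 0.0664), at 4.72 ± 0.97, and of Mki67, Cdk1, Top2a and Mx1 were lost as well (0.0537, 0.0596, 0.0730 and 0.229).

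Interferon-response and antigen presentation genes rose in gel muscle. Of 16 interferon-response genes 11 rose and 0 fell, or 13 adjusted over the list alone (camera adjusted p = 0.000552; adjusted p = 0.702 with an estimated correlation). Ifi27l2a was higher by 3.57 ± 0.61 on the log2 scale and Ifit1, which encodes a protein that binds viral RNA, by 2.27 ± 0.44. Of 12 antigen presentation genes 10 rose and 0 fell, or 12 adjusted over the list alone (camera adjusted p = 9.22e-05; adjusted p = 0.702 with an estimated correlation). The class I gene H2-K1 was higher by 1.10 ± 0.23 and the class II gene H2-Eb1 by 2.98 ± 0.57. Gel library 3 was at -0.73 for the interferon list and -0.30 for antigen presentation, where the other gel libraries were at 1.67 or higher and 1.79 or higher.

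Extracellular matrix and proliferation genes rose as well. Of 25 interstitial matrix genes 13 rose and 0 fell, or 18 adjusted over the list alone (camera adjusted p = 4.92e-06; adjusted p = 0.702 with an estimated correlation). Col14a1, a fibril-associated collagen gene, was higher by 2.13 ± 0.32 on the log2 scale, the proteoglycan gene Bgn by 1.69 ± 0.34 and Lox, which cross-links collagen, by 1.36 ± 0.30. Col1a1 went from 262 ± 126 to 1318 ± 735 CPM, a call lost with the animal as a block (edgeR adjusted p = 0.0577), as was that of Postn (0.103). Col3a1, at 2.13 ± 0.59, lost its call with the 2 groups alone (0.0540) and without gel library 1 (0.0525), 2 (0.0510) or 4 (0.0698) or PBS library 2 (0.0598) or 3 (0.0559). Of 15 matrix-remodelling genes 9 rose and 1 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.702 with an estimated correlation). The protease inhibitor gene Timp1 rose by 2.90 ± 0.44 and its relative Timp3 fell by 0.73 ± 0.17. Of 13 proliferation genes 10 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00245; adjusted p = 0.702 with an estimated correlation). The cyclin gene Ccna2 rose by 2.79 ± 0.43 and Mcm3, a part of the replicative helicase, by 1.21 ± 0.28. Gel library 3 was at -0.38 for interstitial matrix, -0.14 for remodelling and 0.50 for proliferation, where the other gel libraries averaged 1.56, 1.68 and 2.47.

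Genes of developing and regenerating fibres rose in gel muscle. Of 16 such genes 9 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.28e-05; adjusted p = 0.702 with an estimated correlation). Embryonic myosin Myh3 went from 9.71 ± 3.84 to 54.1 ± 32.1 CPM and the myogenic factor Myog from 9.28 ± 6.33 to 31.2 ± 12.9 CPM (edgeR adjusted p = 0.00409 and 0.0117). Cdkn1c, a cell cycle inhibitor gene, rose by 1.61 ± 0.25 on the log2 scale, Dclk1 by 2.32 ± 0.43 and the embryonic troponin gene Tnnt2 by 1.95 ± 0.35. The neonatal myosin gene Myh8, at 2.77 ± 0.51, lost its call with the animal as a block (adjusted p = 0.0548). The list was at 1.67 in gel library 3, 1.68 to 2.76 in the other gel libraries and 0.14 to 1.14 in PBS libraries. Pax7 was at 0.02 ± 0.36 (adjusted p = 0.969), and its sign turned without gel library 1 or 4 (-0.16 and -0.06) or PBS library 1 or 3 (-0.05 and -0.10).

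Of 13 neuromuscular junction genes 4 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0453; adjusted p = 0.702 with an estimated correlation). The call of this list was lost with the animal as a block (adjusted p = 0.100), without gel library 3 (0.196) and without PBS library 3 (0.126). The level of this list was 0.65 in gel library 3 and 0.50 on average in the other gel libraries. Ache, which encodes acetylcholinesterase, rose by 0.83 ± 0.19 on the log2 scale and the receptor subunit gene Chrnb1 by 0.84 ± 0.20. Prima1, whose product anchors acetylcholinesterase to membranes, was the largest fall, from 2.48 ± 0.814 to 0.364 ± 0.172 CPM. The other large falls included Epm2a, a glycogen phosphatase gene, at -2.28 ± 0.31, Phospho1 at -1.79 ± 0.26 and Wfikkn2, which encodes a myostatin-binding protein, at -1.61 ± 0.24. Flrt1, Pdpr, Amd1 and Eif4ebp2 fell by 1.64 to 2.04.

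Lists of fatty acid oxidation, citrate cycle, glycolysis and calcium handling genes were lower in gel than in PBS muscle, each with only some members called. The nuclear respiratory chain list was not called, with 2 of 42 members lower and 1 higher (camera adjusted p = 0.792). Of 22 fatty acid oxidation genes 7 fell and 0 rose, or 8 adjusted over the list alone (camera adjusted p = 0.000188; adjusted p = 0.702 with an estimated correlation), among them Etfdh at -0.85 ± 0.18 and Acsl1 at -0.68 ± 0.18. Of 17 citrate cycle enzymes 5 fell and 0 rose, or 7 adjusted over the list alone (camera adjusted p = 0.000188; adjusted p = 0.702 with an estimated correlation), led by Suclg1 at -0.60 ± 0.14. Sdha, at -0.52 ± 0.15, lost its call with the animal as a block (edgeR adjusted p = 0.0586), with the 2 groups alone (0.0634) and without gel library 2 (0.0572) or PBS library 2 (0.0531). Of 14 calcium handling and excitation genes 7 fell and 0 rose, or 8 adjusted over the list alone (camera adjusted p = 0.000296; adjusted p = 0.702 with an estimated correlation). Jph2 and Jph1, which join the surface and internal calcium membranes, fell by 1.05 ± 0.18 and 0.83 ± 0.17, and the sodium channel gene Scn4a by 0.78 ± 0.17. Of 18 glycolysis and glycogen genes 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.723 with an estimated correlation). Both Pgm2, which rose by 0.95 ± 0.26, and Phkg1, which fell by 0.59 ± 0.17, lost the call without gel library 4 (0.0566 and 0.0544), and Phkg1 also with the 2 groups alone (0.0556). In gel library 3 the fatty acid oxidation, citrate cycle, calcium and glycolysis lists were at 0.11, 0.20, 0.25 and 0.21. They were at -0.39, -0.25, -0.39 and -0.39 on average in the other gel libraries. The fatty acid oxidation, citrate cycle and calcium lists were higher in PBS than in uninjured muscle, and both comparisons use the PBS libraries. In gel against uninjured muscle these lists were not called (camera adjusted p = 0.314, 0.169 and 0.0733). They passed there without gel library 3 (0.0175, 0.00677 and 0.00168).

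The atrophy list as a whole was not called between gel and PBS muscle, with 8 of 18 members lower and 4 higher (camera adjusted p = 0.201). The 4 were Mt1, Mt2, Cebpd and the protease gene Ctsl. Fbxo32 went from 140 ± 31.9 to 63.1 ± 19.7 CPM and Mstn from 12.9 ± 1.31 to 5.49 ± 2.23 CPM (edgeR adjusted p = 0.00325 and 0.00322). Trim63, at -0.58 ± 0.18, lost its call without gel library 1 (0.0614), 2 (0.0682) or 4 (0.0573) or PBS library 3 (0.0635) or 4 (0.0743). Among fast-fibre genes Myh4, the myosin of the fastest fibres, fell by 0.73 ± 0.18, with 4 of 14 members lower and 1 higher (camera adjusted p = 0.0521, and 0.0402 with the animal as a block). This list passed without gel library 1 (0.0464) or 3 (0.00836), PBS library 1 (0.0441), 2 (0.0317) or 4 (0.0255), or any uninjured library (0.0388 to 0.0434). Myh7, the slow myosin gene, was at -1.76 ± 1.39 (adjusted p = 0.371).

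Circadian clock genes were lower and ribosomal protein genes higher in gel than in PBS muscle. Of 15 clock genes 4 fell and 1 rose, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00544; adjusted p = 0.702 with an estimated correlation). Hlf, a clock output gene, fell by 1.33 ± 0.24 on the log2 scale and the clock repressor gene Cry2 by 0.60 ± 0.13. Gel library 3 was at -0.05 for this list and the other gel libraries averaged -0.47. Of 30 ribosomal protein genes 8 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00400; adjusted p = 0.723 with an estimated correlation), with Rpl11 at 0.53 ± 0.13 and Rpl3 at 1.11 ± 0.27. Rn45s was at 114 ± 19.0 CPM in gel muscle and 26.4 ± 7.69 CPM in PBS muscle. Gel library 3, at 103 CPM, was within the range of the other gel libraries. The ribosomal protein list was lower in PBS than in uninjured muscle, and both comparisons use the PBS libraries. In gel against uninjured muscle it was not called (camera adjusted p = 0.184), and passed only without gel library 4 (0.0135).

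In total 4022 genes differed between gel and PBS muscle, 2236 higher and 1786 lower, and 1292 and 188 of these changed at least 2-fold. The groups did not overlap for 2348 of the 4022 genes, and for 20.1% of all genes tested, where chance gives 2.86% if libraries can be exchanged freely. That value leaves out the pairing of gel and PBS legs. The count was 2559 with the 2 groups alone, 2971 with the animal as a block on these groups, and 2456 without gel library 4. The main fit shares 1 estimate of spread over all groups, including the uninjured libraries. The chi-square per gene was 28.0 to 123 between gel libraries and 6.51 to 12.7 between uninjured libraries. Whether this shared estimate made the count higher was not tested. In the simulated counts 27 of 137 calls of this comparison were false.

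**Figure D3:**
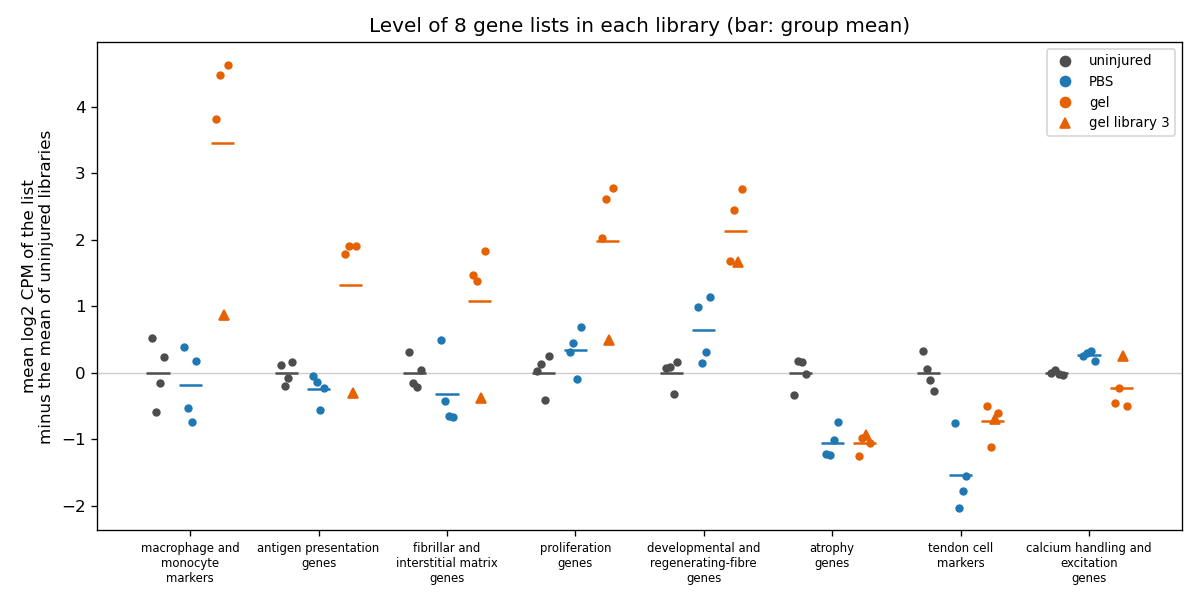
Level of 8 gene lists in each library, as the mean log2 CPM of the members minus the mean of the uninjured libraries (y axis), with points for libraries, a triangle for gel library 3 and bars for group means. For macrophage markers gel libraries 1, 2 and 4 are at 3.81 to 4.63 and gel library 3 at 0.87, while for developmental fibre genes gel library 3, at 1.67, is next to the lowest of the other gel libraries, at 1.68.

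Gel-treated muscle was also compared with uninjured muscle, which shows how far it lay from muscle that had no injury. Uninjured muscle came from other animals, so this comparison cannot part the gel from injury, injection or the set of animals. The atrophy and tendon lists, lower here, were also lower in PBS than in uninjured muscle. Gpnmb, a gene of lipid-laden macrophages, rose by 7.26 ± 1.24 on the log2 scale (SE, n = 4 libraries per group). Mmp13, which encodes a collagenase, rose by 7.40 ± 1.71. Only uninjured library 1 had counts of Mmp13 in the uninjured group, so the size of this rise is uncertain. The protease gene Ctss, with the immune genes Cd48 and C3ar1, Trem2 and Atp6v0d2, rose by 6.30 to 7.13, and Krt8, a keratin gene, had 290 counts in gel muscle and 2 in uninjured muscle, a ratio of 114 with a 95% exact interval of 31.3 to 945. In limma voom the calls of Mmp13, Atp6v0d2, Trem2, Cd48, Ctss and C3ar1 were lost, with adjusted p of 0.0692 for Cd48 to 0.256 for Atp6v0d2. The largest falls were Odf3l2 at -6.18 ± 0.63, Prima1 at -4.11 ± 0.37 and Doc2b at -3.76 ± 0.56. Fkbp5, a chaperone gene induced by glucocorticoids, went from 84.8 ± 19.3 to 8.38 ± 1.89 CPM, and Ppp1r3c, a glycogen-targeting phosphatase subunit gene, from 508 ± 120 to 60.6 ± 18.7 CPM. The complement gene C7, Fam107a and Map3k6 fell by 3.09 to 3.46.

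Of 23 macrophage and monocyte markers 21 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 2.05e-06; adjusted p = 0.725 with an estimated correlation). Lgals3, which encodes galectin-3, rose by 5.58 ± 0.81 on the log2 scale and Folr2 by 2.69 ± 0.46. Of 12 cytokine and chemokine genes 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0330; adjusted p = 0.725 with an estimated correlation, and 0.106 without gel library 1). Tnf rose by 4.87 ± 0.74 and Il15 by 1.12 ± 0.19. Of 16 interferon-response genes 8 rose, or 9 adjusted over the list alone (camera adjusted p = 0.00506; adjusted p = 0.761 with an estimated correlation). Of 12 antigen presentation genes 6 rose, or 12 adjusted over the list alone (camera adjusted p = 0.000342; adjusted p = 0.725 with an estimated correlation), and H2-Aa went from 21.0 ± 4.63 to 166 ± 96.8 CPM. Of 13 proliferation genes 10 rose, or 11 adjusted over the list alone (camera adjusted p = 0.000342; adjusted p = 0.725 with an estimated correlation), with Ccna2 at 2.46 ± 0.43. Of 25 interstitial matrix genes 11 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.000342; adjusted p = 0.725 with an estimated correlation), with Col14a1 at 2.18 ± 0.32 and Ccn2, the member that fell, at -1.24 ± 0.29. Gel library 3 was below the other gel libraries in each of these lists, at 0.87, 0.09, -0.73, -0.30, 0.50 and -0.38 in the order given.

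Of 16 developmental and regenerating-fibre genes 11 rose and 0 fell in gel against uninjured muscle, or 13 adjusted over the list alone (camera adjusted p = 2.20e-07; adjusted p = 0.725 with an estimated correlation). Mymk, the fusion protein gene of myoblasts, went from 0.939 ± 0.455 to 23.3 ± 5.24 CPM, and Myh3 and Myog were higher by 3.06 ± 0.48 and 3.13 ± 0.47 on the log2 scale. Of 13 denervation-response genes 6 rose, also adjusted over the list alone (camera adjusted p = 0.0369; adjusted p = 0.725 with an estimated correlation). Ncam1, a cell adhesion gene, rose by 2.06 ± 0.31 and the foetal receptor subunit gene Chrng by 3.42 ± 0.90. The denervation list shares these genes and Myog with the developmental fibre list, and Chrna1, Chrnd and Musk with the neuromuscular junction list. The calls of these lists are therefore not separate evidence. Of 13 neuromuscular junction genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0330; adjusted p = 0.725 with an estimated correlation), with the agrin receptor gene Lrp4 at 1.10 ± 0.18 and Dok7 at -0.62 ± 0.11. The denervation and junction calls were lost without gel library 3 (camera adjusted p = 0.0840 and 0.146) and without uninjured library 1 (0.0777 and 0.0544). Their levels in gel library 3 were 0.95 and 0.65. Of 14 fast-fibre genes 7 fell, or 10 adjusted over the list alone (camera adjusted p = 0.000342; adjusted p = 0.725 with an estimated correlation), with Actn3, an actinin gene of fast fibres, at -1.06 ± 0.18, Tnnt3 at -0.69 ± 0.13 and Myh4 at -0.91 ± 0.18. The fast-fibre level was -0.19 in gel library 3 and -0.53 on average in the other gel libraries.

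Of 18 atrophy genes 13 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 6.98e-08; adjusted p = 0.556 with an estimated correlation). The log2 fold changes of Cebpd, Trim63, Foxo1 and Ddit4 were -2.23, -1.64, -2.02 and -2.59. Fbxo32 went from 178 ± 42.2 to 63.1 ± 19.7 CPM and Mstn fell by 1.56 ± 0.24. Of 32 proteasome subunits 10 fell, or 11 adjusted over the list alone (camera adjusted p = 0.000234; adjusted p = 0.725 with an estimated correlation), with the activator gene Psme4 at -0.92 ± 0.18 and Psma7 at -0.50 ± 0.12. The proteasome level was -0.05 in gel library 3 and -0.35 on average in the other gel libraries. Of 15 clock genes 6 fell, also adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.725 with an estimated correlation), with Per2 at -1.29 ± 0.18 and Hlf at -1.22 ± 0.24. Of 9 tendon cell markers 4 fell, also adjusted over the list alone (camera adjusted p = 0.0193; adjusted p = 0.725 with an estimated correlation), with Fmod at -1.63 ± 0.35 and Thbs4 at -0.62 ± 0.15. Of 15 matrix-remodelling genes 7 rose and 2 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0419; adjusted p = 0.725 with an estimated correlation), with Timp3 at -1.69 ± 0.17 and Timp1 at 2.01 ± 0.42. That call was lost without gel library 1 (0.0653), 2 (0.0602) or 4 (0.0718), and gel library 3 was at -0.14.

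Endothelial and mural cell markers were lower in gel than in uninjured muscle. Of 12 endothelial markers 3 fell, or 5 adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.725 with an estimated correlation, and 0.0840 without gel library 3). Flt1, a receptor gene for vascular growth factor, fell by 1.49 ± 0.32 and Vwf by 1.00 ± 0.27 on the log2 scale. Of 10 smooth muscle and pericyte markers 1 fell, also adjusted over the list alone (camera adjusted p = 0.0406; adjusted p = 0.725 with an estimated correlation), and the list call was lost without gel library 2 (0.0847), gel library 3 (0.117) or uninjured library 1 (0.0550). The member that fell was Rgs5, at -0.85 ± 0.25, whose call was lost without gel library 3 (edgeR adjusted p = 0.0558), gel library 4 (0.0593), or uninjured library 2 (0.0503) or 3 (0.0514). Gel library 3 was the lowest gel library for both, at -1.03 and -0.97, where the other gel libraries averaged -0.35 and -0.38. Of 18 glycolysis and glycogen genes 3 fell, or 2 adjusted over the list alone (camera adjusted p = 0.0457; adjusted p = 0.819 with an estimated correlation), and that list call was lost without gel library 1 (0.174), 2 (0.0602) or 4 (0.139) or uninjured library 1 (0.0531) or 2 (0.0794). Hk2, which encodes hexokinase 2, was at -0.75 ± 0.21, a call lost without gel library 2 (0.0524) or uninjured library 2 (0.0513), and Phka1 was at -0.74 ± 0.22, a call lost without gel library 1 (0.0513) or 4 (0.0633) or uninjured library 3 (0.0611).

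In total 3449 genes differed between gel and uninjured muscle, 1951 higher and 1498 lower, and 1244 and 322 of these changed at least 2-fold. The groups did not overlap for 2392 of the 3449 genes, and for 23.0% of all genes tested, where chance gives 2.86%. The count was 5341 without gel library 3 and 2275 without gel library 4. In the simulated counts 13 of 133 calls of this comparison were false. With limma voom more genes were lower than higher, 1602 against 1478.

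Some genes that differed between PBS and uninjured muscle differed in the opposite direction between gel and PBS muscle. Reads of the ribosomal RNA precursor Rn45s fell by 1.81 ± 0.20 on the log2 scale in PBS muscle. They were higher by 2.12 ± 0.20 in gel than in PBS muscle, and a part of library preparation in this was not tested. Mt1 and Mt2 were higher in gel than in PBS muscle by 1.88 ± 0.27 and 2.93 ± 0.48, and stood at 165 ± 48.2 and 83.7 ± 33.8 CPM in gel muscle, below the uninjured group. The acute-phase gene Serpina3n fell by 2.88 ± 0.41 in PBS muscle and was higher by 2.22 ± 0.40 in gel than in PBS muscle. Col7a1, an anchoring collagen gene, and Arfip2 had the same directions. Car2, which encodes a carbonic anhydrase, was higher in PBS muscle by 1.23 ± 0.19 and lower in gel than in PBS muscle by 0.98 ± 0.18, and Ubqln2 and Kpna3 likewise. In all 297 genes were called in opposite directions, 163 higher in PBS than in uninjured and lower in gel than in PBS muscle and 134 the other way round, where independent lists give 49.8 and 75.7.

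Both of these comparisons use the PBS libraries, so opposite signs arise with no effect at all. In the same direction 37 genes were called, 16 higher and 21 lower in both, where independent lists give 62.3 and 60.5. The PBS libraries were also split so that each comparison used a different pair. With PBS libraries 1 and 4 in the first comparison, 17 genes were called in opposite and 17 in the same directions, where independent lists gave 13.6 for each. With PBS libraries 1 and 2 there, the counts were 37 and 19, against 28.7 and 26.8. The other splits gave 8 to 20 opposite calls against 1.65 to 9.70, and 1 to 10 in the same direction against 1.59 to 9.47. The covariance of the log2 fold changes across genes, which are not independent replicates, was -0.121. The simulated value was -0.0477 ± 0.00136 (SD), a difference of -0.0732. That SD is over simulations with independently drawn genes and leaves out the spread between animals. The SD of the observed covariance over leaving out each library was 0.0484. In the PBS splits the covariance lay between -0.243 and -0.0549. The correlation was -0.250 and the simulated correlation -0.495. The count of 297 was 864 without gel library 3, 498 with the DESeq2 Wald test, 124, 92 and 148 without PBS library 1, 2 or 3, and 175, 138, 120 and 111 without uninjured library 1, 2, 3 or 4. The covariance was -0.514 with no filter on low counts, and -0.269, -0.196 and -0.228 without PBS library 1, 2 or 4.

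PBS and gel muscle were called in the same direction against uninjured muscle for 410 genes, 156 higher and 254 lower, where independent lists give 54.3 and 50.7, and in opposite directions for 4. Map3k6, Cebpd, Ddit4, Odf3l2, Ucp3 and Trim63 were among those lower in both. With the uninjured libraries split between the comparisons, 54 to 115 genes were called in the same direction, where independent lists gave 2.79 to 9.14. Gel and PBS libraries are taken as legs of the same animals, so both comparisons still set these animals against others. Neither the independent lists nor the simulation includes what legs of an animal share. The covariance was 0.178 against a simulated 0.0308, a difference of 0.148, and the correlation was 0.356 against 0.345.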

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

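The 3 tests on gel library 3 were chosen after its position had been seen. Values of 648 groups of 4 libraries, for the named genes and lists, were searched for a library whose gap to its nearest neighbour took an unusually large share of the range of its group. Chance gives about 1 in 20, or 32.4 groups, and 56 were found, 25 of them in a gel library and 23 of those in gel library 3.

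In gel library 3 the share of the range was 0.925 for Atp6v0d2, 0.923 for C1qa, 0.884 for C1qc, 0.896 for Cd180, 0.859 for Ms4a7 and 0.896 for Tnf. It was 0.936 for Cd74, 0.903 for Ciita, 0.872 for H2-Aa, 0.901 for H2-D1, 0.971 for H2-Eb1, 0.882 for H2-K1 and 0.947 for the antigen presentation list. It was 0.872 for Ifi27l2a, 0.924 for Mx1, 0.839 for Oasl2 and 0.861 for the interferon-response list. It was 0.912 for Col1a1, 0.865 for Col3a1, 0.912 for Lox and 0.854 for Mmp14. In all of these gel library 3 was the lowest gel library, and it was the highest for Fbxo32, at 0.986, and Wfikkn2, at 0.847. The remaining gel values were 0.841 for Chrnd in gel library 4 and 0.879 for Ppp1r3c in gel library 1.

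Gel library 3 lay nearer to the PBS libraries than to the other gel libraries for macrophage and matrix lists, and nearer to the other gel libraries for developmental fibre genes. A swap with a PBS library needs a PBS library with the macrophage level of the other gel libraries, and the highest PBS level was 0.382 against a lowest of 3.81, which argues against a swap. A common reduction of the whole response would keep like shares, and gel library 3 kept 62.2% of the rise over PBS in the developmental fibre list (52.5% to 72.4% over choices of the other gel libraries) and 23.4% in the macrophage list (22.1% to 24.2%), which argues against it. A PBS leg under a gel label would place gel library 3 past the midpoint between PBS and the other gel libraries no more often than a left-out PBS library, on the same genes. With each PBS library left out in turn, gel library 3 was past it in 23.4% to 29.6% of genes and the left-out PBS library in 7.14% to 17.0%. The lowest difference, 10.5 percentage points, was just above the range of the left-out PBS values, 9.86. The bound was chosen after the data were seen and rests on 4 PBS libraries. The test therefore does not decide whether gel library 3 is a PBS leg. An earlier form of this test, which set gel library 3 beside 4 PBS libraries and each PBS library beside 3, gave 46.1% and at most 44.3% beyond all of them and was replaced as unequal. A response of that muscle that differed in time, or that was reduced unequally between lists, stays open and was not tested.

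In PBS libraries the share was 0.834 for Arhgap28 and 0.874 for Ddit4 in library 3, and 0.893 for C7, 0.907 for Ccna2 and 1 for Msr1 in library 2. In library 4 it was 0.903 for Dach2, 0.944 for Fam107a, 0.838 for Jph2, 0.884 for Krt8, 0.889 for Myh4 and 0.842 for Rpl3. In library 1 it was 0.884 for Kpna3 and 0.846 for Mx1.

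In uninjured library 1 the share was 0.913 for C1qc, 0.831 for Dclk1, 0.837 for Ddit4, 0.834 for Fkbp5, 0.858 for Ifit1, 0.856 for Map3k6, 0.867 for Per1, and 1 for both Krt8 and Mmp13. In uninjured library 2 it was 0.891 for Myh8 and 0.934 for the glycolysis list, and in uninjured library 3 it was 0.938 for Frzb, 0.890 for Plaur and 0.948 for Tef. In uninjured library 4 it was 0.883 for Atp1b1, 0.969 for Pgm1, 1 for Sox11 and 0.920 for the ribosomal protein list. A share of 1 arises where the other 3 libraries had 0 counts.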

How the results depend on the processing

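The alternative without gel and PBS libraries 3 was chosen after seeing the data. The cause of each change named here was not tested, except that a stricter threshold leaves fewer calls by construction. The counts of genes changed stayed within 1.5 times under the DESeq2 size factors, either change of the filter and limma voom. PBS against uninjured, with 833 genes, gave 1345 with the DESeq2 Wald test, 2339 with the 2 groups alone, 1412 without libraries 3, 284 at 2-fold or more, 255 at an adjusted p under 0.01, and 378 to 1693 with each library left out. Gel against PBS, with 4022, gave 2559 with the 2 groups alone, 1480 at 2-fold or more, 1782 under 0.01, and 2456 to 5962 with each library left out. Gel against uninjured, with 3449, gave 5437 without libraries 3, 1566 at 2-fold or more, 1682 under 0.01, and 2275 to 5341 with each library left out.

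With an estimated correlation 0 lists passed camera in each comparison, from 6, 14 and 18. With fry, which asks whether a list's genes move on balance, 5, 1 and 5 passed, and the developmental fibre list was the 1 for gel against PBS (adjusted p = 0.0423). PBS against uninjured gave 10 lists without libraries 3 and 6 to 10 with each library left out, with 10 without PBS library 2, PBS library 3 or uninjured library 4. The 297 opposite calls became 498 with the DESeq2 Wald test, 18 as the median of the PBS splits, and 92 to 864 with each library left out. The covariance of -0.121 became -0.514 with no filter, and lay between -0.269 and -0.114 with each library left out.

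The replicate block on gel and PBS was fitted without the uninjured libraries. It ended calls of 15 of the 87 named genes it could test, where the 2 groups alone without a block ended 10 of 87. It gave 17 lists for 14. The fast-fibre, proteasome, basement membrane and cytokine lists were added (camera adjusted p = 0.0402, 0.0369, 0.00834 and 0.0313) and the neuromuscular junction list was ended (0.100). It changed no other list call of that comparison. The count of genes was 2971, above the 2559 of the 2 groups alone. The calls it ended included those of Dok7, Chrne, Sucla2, Pgm1, Mmp14, Plaur, Tef, Rpl14 and Rpl19, with adjusted p of 0.0503 for Plaur to 0.0932 for Tef. Uninjured and injected libraries share only a number, and 3 of 4 PBS libraries correlated best with the uninjured library of their own number, at 0.0882, 0.0433 and 0.0664. The block there gave 2539 genes and 12 lists for PBS against uninjured, and 2618 and 18 for gel against uninjured.

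The sign turned for genes that were not called. For Myh7, PBS vs uninjured, the value was 0.11 with the block, and with each library left out it ranged from -2.343 without PBS replicate 3 to 1.54 without uninjured replicate 4. In the same comparison Col3a1 was at -0.0419 with voom, -0.0299 with the block and -0.40 to 0.29 with each library left out. The ranges were -0.28 to 0.30 for Col1a1, -0.58 to 0.65 for Adgre1 and -0.0572 to 0.62 for Mki67. For gel against PBS, Pax7 was at -0.00465 with the block and -0.16 to 0.18 with each library left out. No named gene that was called turned sign in any alternative. The effect of depth was not tested. Msr1, Sox11 and Krt8 had 2 counts in the lower group of the comparison named for them, so their ratios are given with intervals.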

Other observations

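The tests on the time of day, on dilution and on splits of gel and PBS that part all animals were chosen after their results had been seen, and the genes named in this paragraph and the next were chosen after their values were seen. Growth factor genes moved both ways in gel against PBS muscle, with 3 of 14 higher and 3 lower (camera adjusted p = 0.764). Igf1 and Igf2, which encode insulin-like growth factors, rose by 2.27 ± 0.41 (SE) and 3.03 ± 0.34 on the log2 scale (edgeR adjusted p = 0.00325 and 0.000813). Of 12 satellite cell markers 5 rose and 1 fell (camera adjusted p = 0.148), among them Megf10 at 1.66 ± 0.34, Fgfr4 at 1.41 ± 0.21 and Vcam1 at 1.39 ± 0.34. Of 16 autophagy genes 5 fell and 2 rose (0.273), with the initiating kinase gene Ulk1 at -0.83 ± 0.13, Becn1 at -0.77 ± 0.16 and the lysosomal protease gene Ctsb at 1.09 ± 0.24. Of 13 heat-shock genes 3 fell (0.172): Hsph1, Hspd1 and Bag3, at -0.87 ± 0.18, -0.74 ± 0.16 and -0.87 ± 0.18. Bag3, a co-chaperone gene, rose by 1.03 ± 0.18 in PBS against uninjured muscle.

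The other lists that camera called in no comparison of the fit to all 12 libraries were, for gel against PBS, basement membrane with 3 of 14 higher (camera adjusted p = 0.0835), fibro-adipogenic progenitors with 3 of 12 higher (0.201), neutrophils with 2 of 4 higher (0.267) and B and plasma cells with 1 of 5 higher (0.601). Basement membrane passed with the animal as a block (0.00834) and without gel library 3 (0.00492), PBS library 1 (0.0139) or PBS library 2 (0.0368). Adipocyte, Schwann cell and immediate-early lists each had 1 gene higher (0.337, 0.449 and 0.373), and eosinophil and mast cells and slow-fibre genes had 0 in edgeR, in lists of 4 and 13 (0.764 and 0.742). The nuclear respiratory chain list had 2 of 42 lower and 1 higher (0.792), lipid synthesis 3 lower and 2 higher (0.846), antioxidants 3 and 3 (0.614), transforming growth factor signalling 2 and 2 (0.898), and protein and amino-acid stress 2 lower and 3 higher (0.898). For the growth factor, transforming growth factor, stress and antioxidant lists the median, the mean and the test differed in sign. In these lists Psat1, a serine synthesis gene, was at 1.85 ± 0.38, Sod3, an extracellular superoxide dismutase gene, at 1.16 ± 0.21 and Csf3r, the neutrophil growth factor receptor gene, at 3.78 ± 0.74.

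Genes responsive to glucocorticoids were lower in both injected groups than in uninjured muscle, among them Fkbp5, Ddit4 and Cebpd. A difference in glucocorticoid exposure between uninjured and injected animals is a candidate explanation, tested on 13 further genes chosen before their values were seen. Their median was -0.493 for PBS against uninjured, at percentile 0 among 10000 matched random lists, with 5 lower and 1 higher in edgeR. The median was -0.509 for gel against uninjured, with 7 lower and 1 higher. The random lists were drawn gene by gene, so the percentile does not allow for genes that move together in an animal. A difference in the time of day cannot be told apart, because members of both clock phases had values of either sign: the phase medians differed by 0.0185, while Nr1d1 and Bhlhe41 rose by 1.12 ± 0.23 and 0.67 ± 0.16, so that the bound set for this test was too simple. Uninjured libraries come from other animals, so stress, handling, injury and, for PBS muscle, the gel in the other leg stay open as sources of this difference.

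Calcium handling and excitation genes were lower in gel than in PBS muscle, with a median of -0.47. Dilution of fibre RNA by RNA of other cells may contribute, since macrophage genes rose. As the whole cause it would lower all fibre genes alike, and 6 of 14 fast-fibre genes had a 95% interval above that median: Myl1, Casq1, Pvalb, Tnnc2, Mylpf and Tnni2. The lower bound of Tnnc2, -0.444, was close to the median of -0.469, which was taken without an error. The interval of Actn3, at -0.93 ± 0.18, lay below that median, and those of the other fast-fibre genes spanned it. Mylpf was at 0.41 ± 0.13. A change within the fibres stays a hypothesis, and gel library 3, at 0.25 for the calcium list, lay with the PBS libraries. The calcium list was also higher in PBS than in uninjured muscle. In gel against uninjured muscle it was not called (camera adjusted p = 0.0733), and passed without gel library 3 (0.00168).

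Other splits of the 8 libraries of a comparison into 4 and 4, 35 in number, tested whether chance can be excluded for the comparisons with uninjured muscle. For the number of genes changed, 1 of 35 splits, the real split, gave as many. The counts were 833 against a highest other of 0 for PBS and uninjured, and 3449 against 980 for gel and uninjured. A share of 1 in 35 is the smallest these splits can give, so chance was made less likely but not excluded. Uninjured libraries come from other animals, so the splits cannot part treatment from a difference between the sets of animals. For the number of lists chance was not excluded: 29 of 35 splits gave at least the 6 lists of PBS against uninjured (highest other 16) and 6 the 18 of gel against uninjured (highest other 19). Gel and PBS libraries of a number are taken as legs of the same animal, and the 8 splits that part all 4 animals are too few for a share under 0.05. Of these, 1 gave as many genes, the real split, with 4022 against a highest other of 380, and 6 gave as many lists, with 14 against a highest other of 16.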
